A study of Bos taurus with 55 samples.

How the data were processed

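Mammary biopsies of 28 dairy cows were measured on 1-colour Affymetrix bovine arrays from 2 micrograms of total RNA. The values used here are the deposited probe set intensities on a linear scale. Per the submitters' processing notes, the authors used RMA and GCRMA, without a version and without saying which step each served. Taking log2 of the deposited intensities was the first step made here, and no further scaling was applied.

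The table held 11495 probe sets, of which 112 were controls. Among the other 11383, 703 had values identical to those of another probe set and were merged, which left 10680 for testing. Gene symbols came from a table pairing RefSeq accessions with symbols. It named 6649 of the tested probe sets, covering 6636 genes, and left 4029 without a symbol, because none of the 4050 predicted mRNA accessions (XM) and none of the 441 predicted non-coding accessions (XR) matched. A further 2 tested probe sets stood under several symbols and were not named. For a gene with several probe sets, the one with the highest mean over all arrays was used. FASN, LPIN1 and CSN2 had no named probe set and were not analysed here.

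Samples were grouped by cow, period and period I diet from the labels. All 27 cows with both arrays entered the comparison of the oil period with the control period, which was fitted with limma 3.58.1 in R 4.3.3 with the cow as a fixed block. The cow number pairs the arrays because both come from the same animal. The median correlation of deviations within a cow was 0.192 (from -0.344 to 0.665, over 0.1 in 18 of 27 cows), against 0.0174 between different cows. The change on each oil came from 1 fit with a period effect per period I diet. Differences in that change between oils, and differences between the diets within a period, were tested with limma's moderated F. P-values were adjusted by the Benjamini-Hochberg method over the 10680 probe sets, and a probe set was called at an adjusted p under 0.05. All tests were two-sided, and changes are given as period I minus period II, with the standard error. A gene said to rise or fall was higher or lower in the oil period than in the control period, although the oil period came first. The number of arrays limits their precision.

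Before the data were examined, 19 gene lists and 12 lists of cell type markers were fixed, as were the comparisons and the rule for the genes named. Lists with at least 3 measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the 30 lists tested. Camera with an estimated correlation and limma's fry stood beside it; fry tests whether a list's own genes move, on balance, one way, and does not compare the list with other genes. The change of each list's mean was compared between oils by permutation (100000 draws). Genes named for the oil diets were the 10 with the largest rise and the 10 with the largest fall among called genes that changed one way in at least 75% of cows. For each oil they were the 4 in each direction that changed one way in every cow but at most 1. Between oils they were the 6 with the smallest p. In addition, 15 genes of milk fat and milk synthesis were named in advance, and up to 4 members with the smallest p were taken from each list.

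The fits were tested on simulated data of 10680 probe sets, with 100 changed 1.5-fold and 100 changed 2-fold. For the oil diets against control, 85% of those changed 1.5-fold and 99% of those changed 2-fold were recovered, with 9 unchanged probe sets called. For soybean oil alone the shares were 42% and 82%, for the difference of the response between oils 27% and 65%, and for the oils against each other in period I 47% and 81%. For all of these the change was put into the soybean oil cows in period I only. A shift of 0.2 in the respiratory chain list was recovered, with 0 of the 29 other lists called. The simulated noise was independent between probe sets, so this does not test camera's preset correlation. In the data, the lists called for the oil diets had estimated correlations from 0.048 (apoptosis) to 0.560 (antigen presentation).

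Array batch was read from the array names, which carry 2 prefixes. Period I had 25 arrays of batch 1 and 3 of batch 2, and period II had 2 of batch 1 and 25 of batch 2. The 2 period II arrays of batch 1 (cows 1 and 2) both stood apart, so every value within batch 1 sets the oil period against 2 such arrays and cannot part period from their profile. Array number is the running number in the same names, and is higher by 28 in period II than in period I in every cow. In period I it equals the cow number, so within a period a slope along it is a slope between cows. The cows with an array apart (1, 2, 5, 10, 12 and 15) stand at 15 or lower in that order. The fit with array number leaves the cow out, so it cannot part array order from differences between cows. With the cow and the batch both in the fit of all oils, the period estimate comes only from the 5 cows with both arrays in 1 batch (cows 1, 2, 7, 9 and 14), of which cows 1 and 2 had an array apart, while the residual spread comes from all 27. In the fit by oil the batch term is shared between the oils. None of the 5 cows was on rapeseed oil, where period and batch coincide, so its estimate borrows the batch term from the other oils. RNA quality was taken as the 3 prime minus 5 prime signal of 2 control probe sets.

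Other fits chosen in advance were the fit without the cow, the cow as a random effect, quantile normalization, median centring, leaving out the dimmest 30% or 50% of probe sets, a trended and robust prior, array weights, batch as a term, each batch alone, the 5 cows with both arrays in 1 batch, RNA quality as a covariate, and leaving out each cow. Added after the data were seen were leaving out the 6 cows with an array that stood apart, array number as a covariate without the cow, and both together.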

Results

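Gene expression was measured in mammary biopsies of 28 Holstein-Friesian cows in mid-lactation to ask how unsaturated fatty acids in the diet alter the lactating gland. In period I, which lasted 23 days, the diet held 2.7% of rapeseed oil (a source of oleic acid), soybean oil (linoleic acid), linseed oil (alpha-linolenic acid) or an equal mixture of the 3 oils, with 7 cows on each. All cows then received a control diet without added oil for 28 days, period II. Biopsies came from the end of each period, at a mean of 176 and 204 days in milk. There were 28 arrays from period I and 27 from period II, since 1 cow on linseed oil had none in period II. Every cow received the oil first, so oil feeding, the order of the periods and the stage of lactation changed together.

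The median intensity of the arrays lay between 9.47 and 12.0. Mean correlation with the other arrays was 0.961 or more for 48 arrays and 0.911 to 0.951 for the other 7, which came from 6 cows (period I of cows 5, 10 and 12, and period II of cows 1, 2, 5 and 15). In each of these 7, the list means of milk protein genes and of triacylglycerol synthesis genes lay under the median of their period. The median of these differences over the 7 arrays was -0.89 (from -1.76 to -0.067) and -2.07 log2 units (from -2.55 to -0.32). The list means of markers of luminal epithelium, fibroblasts, macrophages, neutrophils and lymphocytes lay above the median of their period in all 7. The first principal component took 41.7% of the variance and separated these arrays, and the second took 11.3% and rose with array number.

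**Figure D1:**
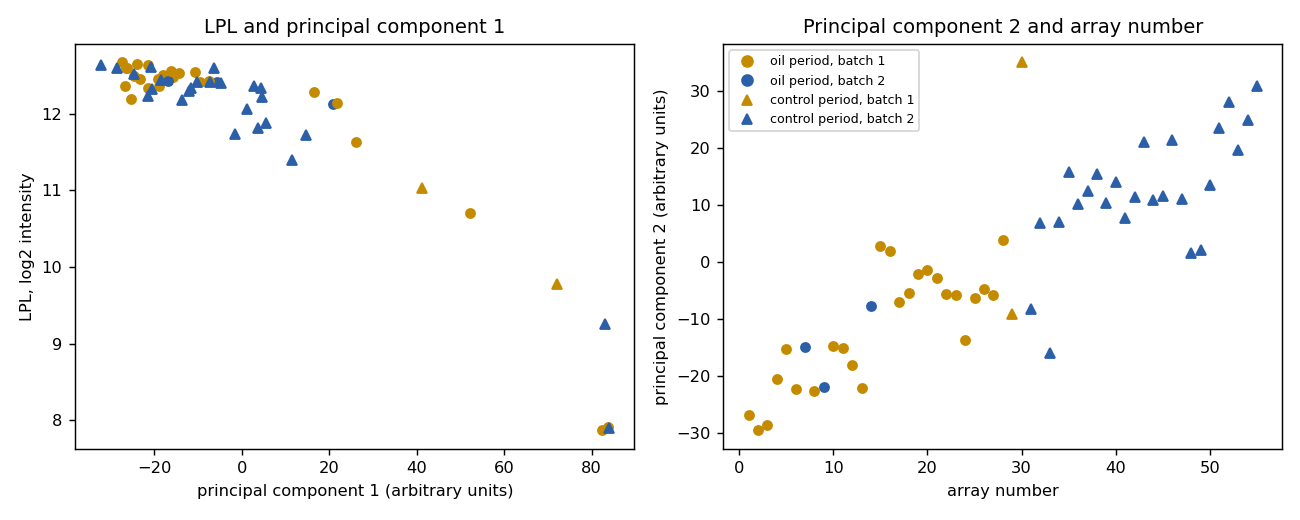
Log2 intensity of LPL against principal component 1 (left) and principal component 2 against array number (right) for 55 arrays, where circles are the oil period and triangles the control period, with batch 1 in ochre and batch 2 in blue. LPL is lowest on the arrays far to the right, and component 2 ranges from -29.6 to 3.84 in the oil period and from -16.0 to 35.1 in the control period.

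Component 2 was correlated with array number within both periods, among 4 relations, which were computed after the trend was seen. In period I (28 arrays) Pearson's r was 0.805 (permutation p = 1e-05, the smallest the draws allow, adjusted p = 4.00e-05) and Spearman's rho was 0.797 (permutation p = 1e-05, adjusted p = 4.00e-05). In period II (27 arrays) r was 0.495 (permutation p = 0.00841, adjusted p = 0.00841) and rho was 0.494 (permutation p = 0.00973, adjusted p = 0.00973). Without the 2 arrays farthest from the median number, r was 0.760 and 0.358. Within batch 1 of period I (25 arrays) r was 0.809 (permutation p = 2.00e-05, adjusted p = 4.00e-05) and rho 0.753 (permutation p = 7.00e-05, adjusted p = 1.40e-04). Within batch 2 of period II (25 arrays) r was 0.647 (permutation p = 4.50e-04, adjusted p = 6.00e-04) and rho 0.615 (permutation p = 0.00155, adjusted p = 0.00207). Without the 2 farthest arrays these r were 0.752 and 0.530. Cows stood in the same order in both periods, so these relations cannot part array order from differences between cows.

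The comparison of the oil diets with the control diet asked which genes differed within the same cow. ARPC3, a subunit of the Arp2/3 complex that nucleates actin filaments, was 2.80-fold higher in the oil period (1.49 ± 0.12 SE, adjusted p = 4.25e-09) and was higher in 27 of 27 cows. ATP5MC1, a subunit of mitochondrial ATP synthase, was 1.89-fold higher (0.92 ± 0.10, adjusted p = 2.51e-07, 26 of 27 cows). MIF, a macrophage cytokine, was 3.84-fold lower (-1.94 ± 0.20, adjusted p = 8.47e-08), and was lower in 26 of 27 cows. The acute phase gene SAA3 fell by 1.75 ± 0.53 (adjusted p = 0.0107) and the secreted glycoprotein gene CHI3L1 by 1.86 ± 0.52 (adjusted p = 0.00655), each lower in 21 cows. Within batches 1 and 2 the changes were -5.56 and -0.22 for SAA3, and -5.31 and -0.54 for CHI3L1. The period II side of batch 1 was only the arrays of cows 1 and 2, both apart, and without the 6 cows the changes were -1.69 and -1.70. ARPC3 was higher by 0.74 (adjusted p = 0.0886) and 0.92 (adjusted p = 0.101), not called in either batch, and MIF was -0.83 (adjusted p = 0.487) and -2.14 (adjusted p = 0.00896). The other large rises were POLR3D (0.96), FBP2 (0.98), PDE12 (0.93), LOC404103 (0.92), KYAT3 (0.92), BDH2 (0.80), BLOC1S5 (0.77) and FST (0.76). The other large falls were LOC789205 (-1.49), the endothelial TGF-beta co-receptor ENG (-1.44), TAGLN2 (-1.41), the immunoproteasome subunit PSMB8 (-1.33), the epithelial sodium channel subunit SCNN1A (-1.32), the junction protein JUP (-1.31) and the lipid carrier APOE (-1.29). With batch in the fit, where the estimate rests on 5 cows, SCNN1A (-0.15, adjusted p = 0.873), FBP2 (0.62, 0.358), BLOC1S5 (0.62, 0.203) and FST (0.86, 0.244) were not called.

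For the oil diets against control, limma called 3669 of 10680 probe sets (34.4%), 2004 higher and 1665 lower in the oil period, in 2336 named genes. Most changes were small, with a median size of 0.29 among the calls. Only 382 exceeded 1.5-fold, 78 higher and 304 lower. With each array centred on its median, 71.9% of calls were higher, against 54.6%. Period and array batch nearly coincided: 597 probe sets were called within batch 1 (25 arrays against 2, both of which stood apart) and 403 within batch 2 (3 against 25), of which 368 and 366 were shared with the full comparison. In the 5 cows with both arrays in 1 batch, limma called 0 (2191 at an unadjusted p under 0.05). With array number as a covariate and without the cow, a fit chosen after the data were seen, 715 were called, 295 of them shared, and MIF (0.49), ENG (1.09), SCNN1A (0.89) and BLOC1S5 (-0.23) took the opposite sign, while ARPC3 stayed higher by 0.88. With the number in the fit and without the 6 cows with an array apart, 11 were called.

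Among genes of milk fat synthesis some fell and others did not pass the test. SCD, the stearoyl-CoA desaturase that makes oleic from stearic acid, had a change of -0.09 ± 0.26 (adjusted p = 0.817), LPL, which releases fatty acids from lipoproteins, 0.18 ± 0.26 (0.630), and the fatty acid binding protein FABP3 0.01 ± 0.32 (0.990). ACACA, the acetyl-CoA carboxylase that starts fatty acid synthesis, was 1.71-fold lower (-0.78 ± 0.27, adjusted p = 0.0275, lower in 20 of 27 cows). SREBF1, a transcription factor of lipid synthesis, fell by 0.48 ± 0.10 (adjusted p = 4.64e-04, 21 cows) and DGAT1, which completes triacylglycerol, by 0.39 ± 0.09 (adjusted p = 8.65e-04, 23 cows). The levels of DGAT1 were dim, 2.19 in period I and 2.58 in period II. All 3 had the opposite sign with array number as a covariate (ACACA 2.21, SREBF1 0.36, DGAT1 0.20), and ACACA and SREBF1 within batch 1 (1.66 and 0.13), where the period II side was 2 arrays apart with low triacylglycerol genes (-1.45 and -0.32 against the period median). With batch in the fit ACACA (-0.57, adjusted p = 0.559), SREBF1 (-0.32, 0.343) and DGAT1 (-0.36, 0.218) were not called. INSIG1 (-0.25), THRSP (-0.02), PPARG (-0.04), GPAM (0.02), GPAT4 (0.14) and the lactose synthase component LALBA (0.07) did not pass the test. With batch in the fit, THRSP was higher by 0.71 (adjusted p = 0.0183), an estimate from 5 cows, 2 of them with an array apart, and fitted on those cows alone it was not called (adjusted p = 0.171). THRSP was also called higher with array number as a covariate. Its levels were dim as well, with means from 2.10 to 2.44 over the oil groups and periods.

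**Figure D2:**
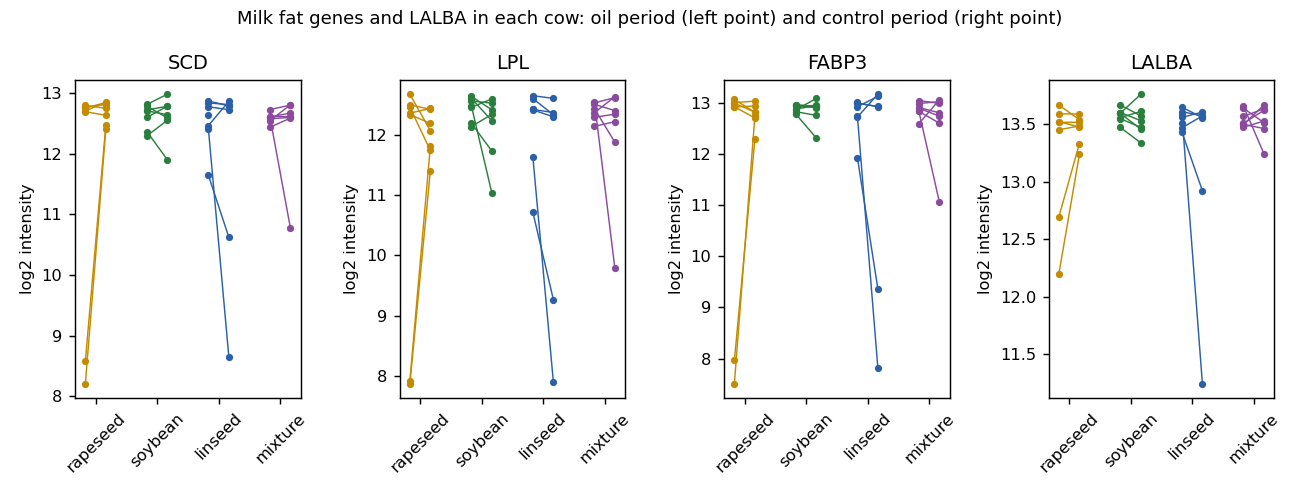
Log2 intensity of SCD, LPL, FABP3 and LALBA in each cow, with the oil period on the left and the control period on the right of each line, by period I oil. Most lines are near level, and the few steep ones belong to cows with an array that stood apart; the mean change over 27 cows was -0.09 for SCD and 0.07 for LALBA.

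Of 11 measured genes of fatty acid synthesis and desaturation, 1 rose (SCD5, 0.53 ± 0.10) and 1 fell (ACACA), with the same counts adjusted over the list alone (list median -0.09, camera adjusted p = 0.838). Of 12 genes of fatty acid uptake, activation and transport, only DBI, an acyl-CoA binding protein, rose (0.24), also when adjusted over the list alone (median 0.13, p = 0.560). Without the 6 cows with an array apart, 5 genes of this list rose. Among 18 genes of triacylglycerol synthesis and the milk fat globule 1 rose (DGAT2, 0.26) and 4 fell, or 1 and 3 adjusted over the list alone (median -0.10, p = 0.334). The falls included AGPAT1 (-0.87) and the lipase PNPLA2 (-0.59). Among 14 lipid regulators 2 rose and 4 fell, with the same counts adjusted over the list alone (median -0.05, p = 0.312). NR1H2, a liver X receptor, fell by 0.63 in 26 of 27 cows, MBTPS1 by 0.27, and MBTPS2 rose by 0.32. AGPAT1 and NR1H2 had the opposite sign within batch 1, against 2 arrays apart (0.22 and 0.03), and also with array number, as did PNPLA2 (0.25). MBTPS2 was -0.03 within batch 2. Triacylglycerol genes took a list median of 0.59 with array number as a covariate (camera adjusted p = 0.0111).

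Of 15 genes of cholesterol synthesis and uptake 2 rose, among them ACAT2 (0.37 ± 0.11), while EBP (0.29) and FDPS (0.31) did not pass, with 2 rises adjusted over the list alone (median 0.23, p = 0.290). Without the 6 cows with an array apart, 6 genes of this list rose. With batch in the fit, where the estimate rests on 5 cows, 2 of them with an array apart, camera called the list higher (median 0.63, adjusted p = 0.00295), as it did with array number as a covariate (0.65, adjusted p = 0.00388), although ACAT2 was then -0.33. Of 6 genes of cholesterol efflux 1 fell, APOE, as over the list alone (median -0.01, p = 0.754). Of 20 genes of fatty acid oxidation 7 rose and 2 fell, and 9 and 2 adjusted over the list alone. CPT2 (0.41) and the carnitine carrier SLC25A20 (0.45) rose and ACAA1 fell by 0.41. Camera did not call the list (median 0.13, adjusted p = 0.181), whereas fry, which sets its genes against no others, gave an adjusted p of 1.46e-04. Fry called 11 of the 30 lists tested, so such a call was not particular to this list. Array number reversed CPT2 (-0.06), SLC25A20 (-0.041) and ACAA1 (0.23).

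Genes of the respiratory chain were higher in the oil period. Of 27 measured, 12 rose and 2 fell, with the same counts adjusted over the list alone (list median 0.11, camera adjusted p = 0.0232, mean higher in 22 of 27 cows). With an estimated correlation the adjusted p = 0.534. NDUFB8 (0.31 ± 0.03) and NDUFA1 (0.38 ± 0.05), both of complex I, were higher in 27 of 27 cows, and ATP5F1C of ATP synthase rose by 0.34, whereas UQCRC1 of complex III fell by 0.76. UQCRC1 was 0.24 with array number as a covariate. The list median was 0.18 within batch 1, against 2 arrays apart, and 0.08 within batch 2. Of 12 genes of milk proteins and lactose synthesis 1 rose and 2 fell, also when adjusted over the list alone (median -0.01, p = 0.634). UGP2 rose by 0.42, PGM1 fell by 0.37 and the antimicrobial milk protein LTF fell by 0.63, and PGM1 was 0.09 with array number as a covariate. Of 17 ribosomal protein genes 1 rose and 2 fell, or 1 and 1 adjusted over the list alone (median 0.05, p = 0.634), and with batch in the fit, an estimate from 5 cows, their median was -0.14 (adjusted p = 0.0331).

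Lower in the oil period were lists of apoptosis and antigen presentation. Of 18 genes of apoptosis and involution 0 rose and 6 fell, or 1 and 7 adjusted over the list alone (median -0.17, camera adjusted p = 0.0393, mean lower in 23 of 27 cows). The call was lost with an estimated correlation (adjusted p = 0.534), with batch in the fit (-0.23 from 5 cows, adjusted p = 0.0993) and without the cow block (-0.18, adjusted p = 0.0534). TNFRSF1A fell by 0.66, the lysosomal protease CTSB by 0.46 and CEBPD by 0.53. Of 12 genes of antigen presentation 0 rose and 4 fell, or 0 and 5 adjusted over the list alone (median -0.24, camera adjusted p = 0.0393, mean lower in 19 of 27 cows), a call lost with an estimated correlation (adjusted p = 0.830). CD74, the class II invariant chain, fell by 1.22, TAPBP by 0.42 and TAP1 by 0.53. Within batches 1 and 2 the list medians were -0.44 and -0.24 for apoptosis, and -1.33 and -0.23 for antigen presentation, with the batch 1 values set against 2 arrays apart.

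Among cell type markers, those of luminal epithelium, endothelium and fibroblasts were lower in the oil period. Of 9 luminal markers 0 rose and 4 fell, also when adjusted over the list alone (median -0.47, camera adjusted p = 0.00737, but 0.534 with an estimated correlation, mean lower in 18 of 27 cows), with falls of KRT7 (-0.76), KRT19 (-0.47), CLDN3 (-0.49) and ELF3 (-0.48). Of 10 endothelial markers 0 rose and 5 fell, also over the list alone (adjusted over the list alone, median -0.30, camera adjusted p = 0.00164, but 0.534 with an estimated correlation, mean lower in 24 cows), among them ENG, ESAM (-0.66), CDH5 (-0.51) and TIE1 (-0.34). Of 11 fibroblast and matrix genes 0 rose and 7 fell, adjusted over the list alone too (median -0.33, camera adjusted p = 0.0326, but 0.828 with an estimated correlation, mean lower in 21 cows), with COL1A1 (-1.21), FBLN1 (-1.13), BGN (-0.61) and SPARC (-0.44). Medians within batches 1 and 2 were -1.26 and -0.45 for luminal markers, -0.09 and -0.22 for endothelium, and -1.14 and -0.34 for fibroblasts. The 2 period II arrays of batch 1, both apart, had luminal markers 0.79 and 0.83 and fibroblast genes 0.54 and 1.41 above the period median. With array number as a covariate the endothelial median was 0.08 (adjusted p = 0.345), and CLDN3 (0.30), CDH5 (0.28) and TIE1 (0.08) took the opposite sign.

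**Figure D3:**
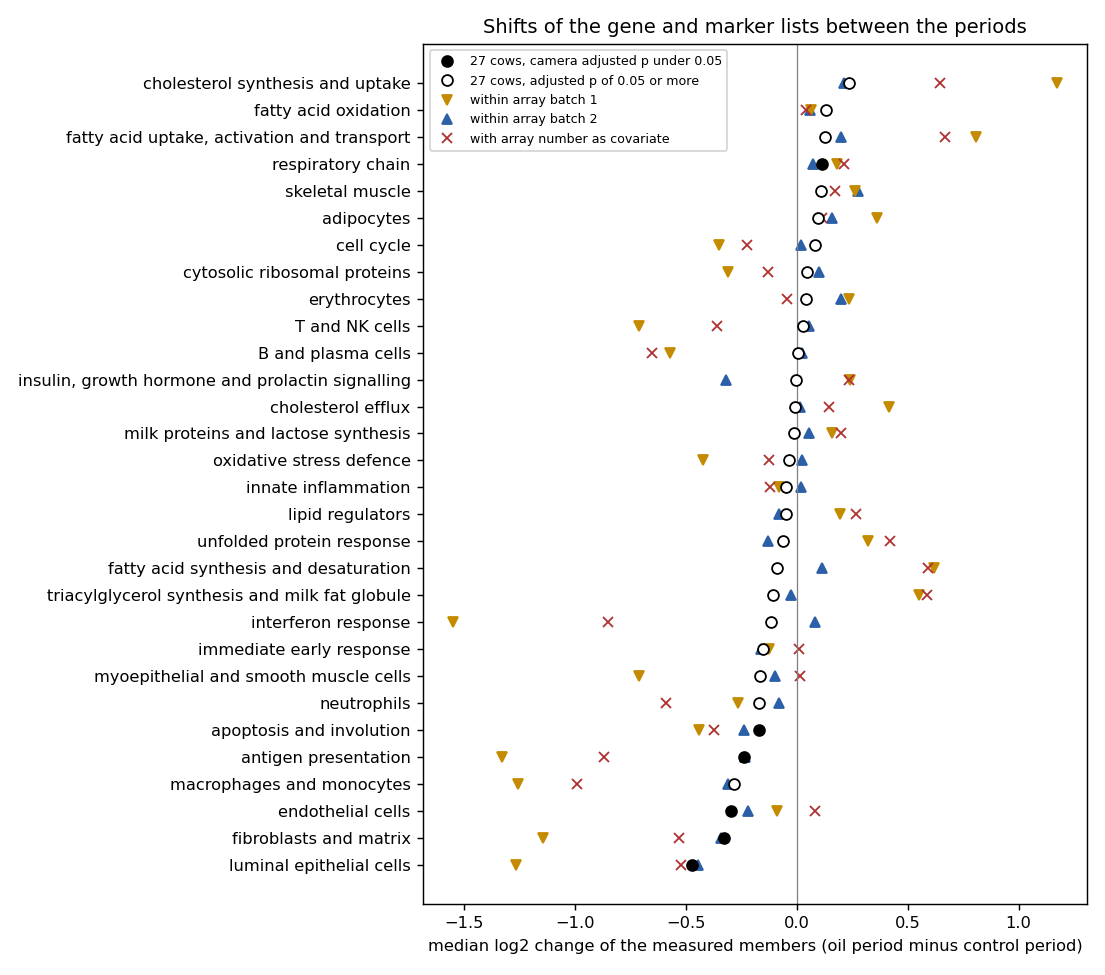
Median log2 change of the measured members of each list, oil period minus control period, with circles for the fit with 27 cows (filled where camera's adjusted p was under 0.05), triangles for batch 1 (ochre) and batch 2 (blue), and crosses for the fit with array number. The filled circles run from -0.47 for luminal epithelial cells to 0.11 for the respiratory chain, and the cross for endothelial cells lies at 0.08.

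The other marker lists were not called by camera in the fit with the cow alone. With batch added, myoepithelial markers were called lower (-0.78, adjusted p = 0.00398) and skeletal muscle markers higher (0.41, adjusted p = 0.00295), from the 5 cows with both arrays in 1 batch. Of these, cow 2 had a period II array apart with myoepithelial markers 1.28 above the period median. With array number, markers of macrophages (-0.99, adjusted p = 0.0264), T and NK cells (-0.36, adjusted p = 0.00661) and B and plasma cells (-0.65, adjusted p = 0.0327) were called lower. Adjusted over the list alone, as over all probe sets, no neutrophil (6 measured) and no B or plasma cell gene (6) passed, with camera adjusted p of 0.62 and 0.737. Of 10 macrophage and monocyte markers 2 fell, FCER1G (-0.75) and C1QA (-0.65) (median -0.28, p = 0.224), of 9 T and NK cell markers 1 rose (CD5, 0.20) and 1 fell (CD3E, -0.51, but 0.0094 within batch 2) (p = 0.954), and of 8 myoepithelial markers 1 fell, KRT17 (-0.75) (p = 0.312). Of 9 adipocyte markers 3 rose and 2 fell (p = 0.560), among them LIPE (0.29), PLIN1 (0.26) and RBP4 (-0.62), and PLIN1 was -0.024 with array number. Of 5 erythrocyte markers 1 rose and 1 fell (p = 0.634), of 2 keratinocyte markers 1 rose (DSG1, 0.15), too few for camera, and of 9 skeletal muscle markers 3 rose (p = 0.138). MYL1 (0.38) and MYH1 (0.31) were dim, with levels of 2.12 and 2.36 in period I.

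The change against control was also fitted for each oil. On rapeseed oil ARPC3 (1.38), TM2D2 (1.15), ATP5MC1 (1.15) and BDH2 (1.06) had the largest rises, each higher in 7 of 7 cows, and SCNN1A (-2.14), MIF (-1.89), the glutathione synthetase gene GSS (-1.82) and ENG (-1.81) the largest falls, each lower in 7 of 7. SREBF1 fell by 0.75 ± 0.18 (adjusted p = 0.0193, 6 of 7 cows) and DGAT1 by 0.60 ± 0.17 (adjusted p = 0.0466, 7 of 7 cows). SCD (-1.18 ± 0.46, adjusted p = 0.142) and FABP3 (-1.28 ± 0.58, adjusted p = 0.205) did not pass, and without the 6 cows with an array apart they stood at -0.03 and 0.12. Without these cows SCNN1A (-1.64, adjusted p = 0.0610), GSS (-1.34, 0.211), SREBF1 (-0.54, 0.0860) and DGAT1 (-0.64, 0.0698) were not called. For rapeseed oil against control 414 probe sets were called, 165 higher and 249 lower, against 161 without the cow block. Without cows 4, 10, 12, 23 or 27 in turn there were 182, 127, 165, 241 and 133. With array number as a covariate limma called 0 (1094 at an unadjusted p under 0.05), and SCNN1A (0.12), MIF (0.49), ENG (0.73) and SREBF1 (0.05) had the opposite sign.

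On soybean oil the class II histocompatibility gene BOLA-DQA5 (2.68, higher in 6 of 7 cows), the growth inhibitor MSTN (1.82, 6 of 7), the lysosomal protease CTSL (1.79, 7 of 7) and ARPC3 (1.71, 7 of 7) had the largest rises. MIF (-2.67), LOC789205 (-2.37), COL1A1 (-2.30) and JUP (-2.21) had the largest falls, each lower in 7 of 7 cows. Without the 6 cows BOLA-DQA5 (2.27, adjusted p = 0.107) and MSTN (1.52, 0.0858) were not called. SREBF1 fell by 0.73 ± 0.18 (adjusted p = 0.00813, 7 of 7 cows), and SCD (0.01 ± 0.46) and LPL (0.31 ± 0.49) did not pass. For soybean oil against control 1443 probe sets were called, 672 higher and 771 lower. Without cow 2, 647 were called, and without cow 24, 921. With array number as a covariate 14 were called, and SREBF1 was 0.07.

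On linseed oil, with 6 pairs, ARPC3 (1.81, 6 of 6 cows), the metalloprotease ADAM12 (1.13, 6 of 6), SZRD1 (0.93, 5 of 6) and ATP5MC1 (0.89, 6 of 6) had the largest rises. MIF (-1.76), LIN37 (-1.29), the lectin LGALS4 (-1.22) and RBM42 (-1.17) had the largest falls, each lower in 6 of 6. Without the 6 cows ADAM12 (0.92, adjusted p = 0.145), SZRD1 (0.50, 0.355), ATP5MC1 (0.59, 0.236), LIN37 (-0.89, 0.183) and RBM42 (-0.94, 0.120) were not called. For linseed oil against control limma called 138 probe sets, 43 higher and 95 lower, against 29 without the cow block. Without cows 5, 7, 8, 15, 21 or 25 in turn there were 78, 26, 41, 21, 240 and 48. With array number as a covariate 21 were called, and MIF (0.63) and RBM42 (0.15) had the opposite sign.

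On the mixture ARPC3 (1.09), the complex I subunit NDUFS4 (0.78) and the mitochondrial ribosomal proteins MRPS14 (0.71) and MRPL16 (0.65) rose in 7 of 7 cows, and PTPA was the single named gene that fell (-0.68, lower in 6 of 7). For the oil mixture against control limma called 16 probe sets, 14 higher and 2 lower (1455 at an unadjusted p under 0.05), and 1 with array number as a covariate. Without cows 3, 6, 11, 14, 16 or 20 in turn there were 1, 1, 10, 7, 63 and 10. No oil had enough arrays of both periods in 1 batch for a value within a batch, since batch 2 held at most 1 period I array per oil and none on rapeseed oil.

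Several lists were called on more than 1 oil. On rapeseed oil triacylglycerol synthesis (median -0.61, camera adjusted p = 6.28e-04; with an estimated correlation the adjusted p = 0.416), milk proteins (-0.26, p = 0.00559; estimated correlation p = 0.637), apoptosis (-0.14, p = 0.0359; estimated correlation p = 0.416) and endothelial cells (-0.49, p = 7.85e-08; estimated correlation p = 0.0253) were lower. Cows 10 and 12 of this group had period I arrays apart, with triacylglycerol genes at -2.39 and -2.55 and milk proteins at -0.92 and -1.43 against the period median, and the mean of milk proteins was lower in 4 of 7 cows. The respiratory chain (0.16, p = 0.0359) and ribosomal proteins (0.18, p = 0.0359) were higher, with p of 0.573 and 0.668 with an estimated correlation. On soybean oil apoptosis (-0.27, p = 0.0151), luminal epithelium (-0.62, p = 0.00668), endothelium (-0.32, p = 0.00743) and fibroblasts (-0.66, p = 0.00234) were lower, with adjusted p of 0.403, 0.611, 0.607 and 0.611 with an estimated correlation. CTSL, a member of the apoptosis list, went the other way on this oil (1.79, higher in 7 of 7 cows). Cow 2 had a period II array apart, with apoptosis genes 0.36, luminal markers 0.83 and fibroblast genes 1.41 above the period median. On linseed oil milk proteins were higher (0.38, p = 0.0471) and luminal epithelium lower (-0.68, p = 0.0144), with adjusted p = 0.798 for both with an estimated correlation. Cows 5 and 15 had period II arrays apart, with milk proteins at -0.89 and -1.76 against the period median, and without the 6 cows camera called 0 linseed lists (6 at an unadjusted p under 0.05). On the mixture the respiratory chain was higher (0.13, p = 0.00988), with adjusted p = 0.831 with an estimated correlation.

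Whether the response itself differed between the oils was tested directly. THAP6, which encodes a protein with a THAP domain, had the smallest p, with changes of 1.00 ± 0.24 on soybean oil (higher in 7 of 7 cows) and -1.09 ± 0.26 on linseed oil (lower in 6 of 6), but its adjusted p over all 4 oils was 0.502. It was also the single probe set called among the 6 pairs of oils, for soybean minus linseed oil (2.09, 95% interval 1.36 to 2.82, adjusted p = 0.0367). The next genes by p were SEC22C, ZPR1, ZFAND2A, SNAPIN and GPT, the last with adjusted p = 0.948. Over all 4 oils limma called 0 probe sets (486 at an unadjusted p under 0.05). For SCD the response on rapeseed minus linseed oil was -1.94 (95% interval -3.34 to -0.54, adjusted p = 0.638), and 0.03 (-0.24 to 0.30) without the 6 cows. No list's response differed after adjustment; adipocyte markers came nearest (F = 5.80, permutation p = 0.0033, adjusted p = 0.0990), with mean changes of -0.16 on rapeseed oil, 0.05 on soybean oil, 0.06 on linseed oil and 0.14 on the mixture. Endothelial markers (permutation p = 0.0425), fatty acid uptake (0.0460) and milk proteins (0.0464) each had an adjusted p of 0.348.

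Calls on different oils overlapped and shared direction. Of 414 calls on rapeseed and 1443 on soybean oil 287 were shared, against 55.9 for independent lists, all in the same direction. Soybean and linseed oil shared 102 calls, 101 in the same direction (18.6 for independent lists), and rapeseed and linseed oil 61 (5.35). The mixture shared 9 calls with rapeseed (0.620), 12 with soybean (2.16) and 5 with linseed oil (0.207). Of the calls on rapeseed, soybean, linseed and mixture, 98.3%, 98.0%, 99.3% and 100% had the same sign as the mean change of the other oils. The counts for independent lists are a low reference, because the changes come from 1 fit that shares the residual spread of each probe set. All oils also share the same step between periods, with nearly the same step in batch and array number. The overlap therefore does not show an effect common to the oils.

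The diets were compared with each other in period I, while they were fed. SLC39A12, a zinc transporter, had the smallest p (mean level 3.45 on soybean oil against 2.02 on rapeseed oil, 2.03 on linseed oil and 2.36 on the mixture, adjusted p = 1.00), followed by SEC22C, UBE2G2, AGA, ZFY and THAP6. Limma called 0 probe sets (277 at an unadjusted p under 0.05), also within the arrays of batch 1 (265). For SCD the difference of rapeseed minus soybean oil was -1.11 (95% interval -2.25 to 0.02), and 0.09 (-0.11 to 0.30) without the 6 cows.

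In period II, when all cows received the control diet, the former oil groups were compared. COLEC12, a scavenger receptor, had the smallest p (level 5.16 after linseed oil against 4.05 after rapeseed, 4.39 after soybean and 4.41 after the mixture, adjusted p = 0.976), followed by FAM114A2, TBCD, MCOLN1, PUDP and PHETA2. Limma called 0 probe sets (397 at an unadjusted p under 0.05). Batch 1 held 2 of the 27 arrays, too few for a value, and the 25 arrays of batch 2 were not fitted alone.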

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

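The tests of array batch, of linear drift and of a lower share of epithelium were chosen after the result was seen, and so were the fits with array number and without 6 cows. The bound that was to exclude drift as the whole cause was written beforehand but was changed after its values were seen, and it is counted here as chosen afterwards.

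The first pattern is the broad difference between period I and period II, with 3669 probe sets called against at most 677 in the 99 other of 100 random choices of each cow's sign, so chance can be excluded. Array batch alone is argued against, since of 2876 probe sets called in the 22 cows split over batches 89.2% changed the same way in the 5 cows with both arrays in 1 batch, with a median ratio of 1.12. Linear drift along array number stays open. The coefficient of the period change on the expected change was 0.101 in 27 cows (0.115 corrected for noise in the slopes). Without the 6 cows with an array apart it was 0.377 (0.562 corrected). The SD over random orders was 0.276 and 0.271, and 39 and 8 of 100 random orders were as high. The correlation of the 2 changes was 0.187 in 27 cows, under the 95% point of the random orders (0.359). Without the 6 cows it was 0.499, above the highest random order (0.402). Of the called probe sets, 68.8% and 81.3% had the expected sign. The slopes run along the cow number, so drift and differences between cows cannot be told apart. The squared correlation over called probe sets was 0.196 in 27 cows, and the uncorrected coefficient met the original bound against drift as the whole cause in both sets, but noise in the slopes lowers that coefficient, and without the 6 cows neither the corrected one nor the squared correlation of 0.509 met it, and 11 probe sets were called with the number in the fit. Diet, the order of the periods and stage of lactation cannot be told apart, because all 27 cows received the oil first. The bacterial hybridisation controls were also higher in period I, by 0.44 and in 22 of 27 cows. Their bearing on the calls was not tested.

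The second pattern is the 7 arrays that stood apart, with low milk genes and high markers of luminal epithelium, fibroblasts and immune cells. RNA quality as the cause in all 7 is argued against, since the 3 prime minus 5 prime signal lay outside the range of the other arrays of its period in 2 of 7. Both of these, period II of cows 1 (-0.757) and 5 (-0.146), lay above that range (highest -0.966). The array of cow 1 was of batch 1, whereas all arrays that set this range were of batch 2. The value of cow 1 lay inside the range of the other arrays of period I (-1.34 to -0.54), most of which were of batch 1. Cow 5 in period II also had the lowest mean correlation, 0.911. For these 2 arrays RNA quality stays open, and the measure rests on 2 control probe sets. Luminal markers lay above the median of their period in 7 of 7, by a median of 0.83, which argues against a loss of luminal signal alongside the milk genes. It cannot decide the share of epithelium, because array signal is relative to the other transcripts. By the median over the 7 arrays, fibroblast (1.40), neutrophil (1.12) and macrophage (1.01) markers lay further above than luminal ones. T and NK cell (0.66) and B and plasma cell (0.68) markers lay less far above, and endothelial markers lay above the median in 2 of 7. This order did not hold on every array. Luminal markers ranged from 0.66 to 1.14, fibroblast from 0.54 to 2.08, neutrophil from 0.14 to 1.90 and macrophage markers from 0.55 to 1.48. Milk protein genes ranged from -1.76 to -0.067, so they were not clearly low on all 7. A candidate explanation is secretory tissue with reduced milk synthesis and inflammation, since neutrophil markers (median 1.12) and macrophage markers (1.01) were above the median in 7 of 7 arrays. The labels give no health record, so no biological explanation was tested.

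The last pattern is the excess of small higher calls among dim probe sets: among the 3560 with the lowest mean, 972 were higher and 265 lower, and 8 of these exceeded 1.5-fold, against 658 and 611 among the 3560 with the highest mean. Background or summary in the deposited values fits with the test made, since 46 of 48 dim control probe sets were higher in period I, with a median of 0.14 and a higher median in 23 of 27 cows, against 0.07 for the 3560 dimmest probe sets. Small rises of dim genes, such as MYL1 and MYH1, may therefore be technical.

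Random signs per cow argue against chance for 3 single oils. Rapeseed oil called 414 against at most 73 in 64 splits, soybean oil 1443 against 471 in 64, and linseed oil 138 against 12 in 32. Only 1 split in each case, the real one, was as large. That is the smallest share these few splits allow, and it was not adjusted over the oils. The mixture called 16 against at most 14 in 64 splits, so only 1 split was as large. Its count was 1 without cow 3 or cow 6 and 63 without cow 16, so the argument against chance there rests on few calls. For the difference of the response between oils, 0 limma calls (486 at an unadjusted p under 0.05) stood against at most 2 in other splits, for the oils in period I 0 (277) against 2, and for the former groups in period II 0 (397) against 16. With 0 calls every split, 100 of 100, is as large by construction, so these splits test nothing.

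Among 48 tests of a single cow far from the others of its group, 12 passed, where chance gives about 5%, and 10 of the 12 were in cows with an array apart. On linseed oil cow 15 had a change of 3.78 in SCD (the others from -0.40 to 1.03) and of 2.34 in LALBA. On the mixture cow 1 had changes of 1.84 in SCD, 2.76 in LPL, 1.78 in FABP3, 2.41 in INSIG1, 1.06 in THRSP and 1.44 in GPAM, and cow 11 had -1.26 in DGAT1. On soybean oil cow 2 had changes of 1.45 in LPL and 0.47 in FABP3, and cow 17 had -0.88 in PPARG.

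The response of THAP6 differed between soybean and linseed oil by 2.09, in 1 of 6 contrasts between pairs of oils (adjusted p = 0.0367 within that pair); over all 4 oils its adjusted p was 0.502. The bacterial hybridisation controls, outside the comparisons, were higher in period I by 0.44 (SD 0.694), in 22 of 27 cows, with 7 probe sets from 0.22 to 0.75. They are not cow transcripts, so the arrays of the periods also differed in a way that need not come from the tissue.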

How the results depend on the processing

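The fits without the 6 cows with an array apart, with array number as a covariate, and with both, were chosen after seeing the data; the other settings were planned. Differences of the response between oils, and between diets within either period, stayed at 0 limma calls in every setting run (486, 277 and 397 at an unadjusted p under 0.05 as reported). Of 99 genes named for the oil diets, 96 stayed the same without the 6 cows (3 became significant), 99 with quantile normalization and 95 without the cow (4 lost the call). With batch in the fit, estimated from 5 cows, 33 lost the call and 3 reversed; within batch 1, 57 and 9; within batch 2, 72 and 2; in the 5 cows with both arrays in 1 batch, 84 and 2. With array number 27 reversed, 44 lost the call, 27 stayed and 1 became significant. That covariate nearly coincides with period, so precision was lost as well, and within a period it follows the cow number. Where a count or sign moved, the cause was not tested, except that filters leave fewer probe sets and batches fewer arrays. Dim signal limits the smallest changes.

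Counts for oil diets against control, rapeseed oil against control, soybean oil against control, linseed oil against control and oil mixture against control moved as follows. Without the cow block, the replicate block, rapeseed oil gave 161 and linseed oil 29 calls, with 3 rapeseed and 4 linseed lists; that block changed no other count by over 1.5 times. With the cow as a random effect the mixture gave 78. Quantile normalization gave 78 for linseed oil and 28 for the mixture, with 0 mixture lists. Median centring gave 9 soybean, 4 linseed and 6 mixture lists. Leaving out the dimmest 30% gave 9 for the mixture, and the dimmest 50% 1825 for all oils, 858 for soybean oil and 7 for the mixture. The trended robust prior gave 28 for the mixture. Array weights gave 836 for rapeseed oil, 238 for linseed oil and 144 for the mixture. Batch in the fit gave 1645 for all oils, 76 for rapeseed oil and 102 for the mixture, with 10 soybean, 8 linseed and 7 mixture lists. The 76 rests on a batch term from cows on the other oils, so it cannot part period from batch on rapeseed oil. RNA quality as covariate gave 142 for rapeseed and 214 for linseed oil. Within batch 1 there were 597, within batch 2 403, and in the 5 cows with both arrays in 1 batch limma called 0 (2191 unadjusted). Without the 6 cows linseed oil gave 53 and the mixture 67, with 0 linseed lists. Array number as covariate gave 715 for all oils, 0 for rapeseed oil (1094 unadjusted), 14 for soybean oil, 21 for linseed oil and 1 for the mixture, with 13 lists for all oils, and without the 6 cows 11. Camera with an estimated correlation called 0 lists for all oils (2 unadjusted), 1 for rapeseed, 0 for soybean (2), 0 for linseed (0) and 0 for the mixture (1).

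Leaving out 1 cow at a time gave 3391 to 3939 calls for oil diets against control, and 0 to 0 for the response between oils and for period I. The count for rapeseed oil against control ranged from 127 (without cow 10) to 438, with 182, 165, 241 and 133 without cows 4, 12, 23 and 27. That for soybean oil against control ranged from 647 (cow 2) to 1441, with 921 without cow 24. That for linseed oil against control ranged from 21 (cow 15) to 240 (cow 21), with 78, 26, 41 and 48 without cows 5, 7, 8 and 25. That for oil mixture against control ranged from 1 (cows 3 and 6) to 63 (cow 16), with 10, 7 and 10 without cows 11, 14 and 20.

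Signs reversed as follows (log2 changes in the alternative), counting only genes and lists called in at least 1 of the fits compared, and lists by camera's direction; others, such as SCD and INSIG1, changed sign without being called in either. With batch in the fit: THRSP 0.71, FOSB 0.063, HERPUD1 0.032, and the ribosomal list -0.14. Within batch 1, where the period II side is the 2 arrays apart of cows 1 and 2: SCNN1A 0.44, ACACA 1.66, SREBF1 0.13, NR1H2 0.035, AGPAT1 0.22, FOSB 0.25, TXNRD1 0.35, PRDX1 -0.13 and HERPUD1 0.15. Within batch 2: MBTPS2 -0.035 and CD3E 0.0094. In the cows with both arrays in 1 batch: FOSB 0.063 and HERPUD1 0.032.

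With array number as covariate: BLOC1S5 -0.23, MIF 0.49, ENG 1.09, SCNN1A 0.89, ACACA 2.21, SREBF1 0.36, THRSP 0.75, DGAT1 0.20, ACAT2 -0.33, CPT2 -0.058, SLC25A20 -0.041, ACAA1 0.23, UQCRC1 0.24, NR1H2 0.24, AGPAT1 0.87, PNPLA2 0.25, PGM1 0.093, CLDN3 0.30, TIE1 0.081, CDH5 0.28, JUND 0.24, AKT1 0.69, IGF2 0.20, TXNRD1 0.29, PRDX1 -0.060, PLIN1 -0.024 and RELA 0.10. By oil, rapeseed SCNN1A 0.12, MIF 0.49, ENG 0.73 and SREBF1 0.047, soybean SREBF1 0.068, and linseed MIF 0.63 and RBM42 0.15. Lists: triacylglycerol synthesis and milk fat globule 0.59, unfolded protein response 0.42, cell cycle -0.22 and endothelial cells 0.081. The medians of T and NK cells (0.027 to -0.36) and of B and plasma cells (0.0063 to -0.65) also changed sign, with camera's direction lower in both fits.

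With array number and without the 6 cows, for oil diets against control: BLOC1S5 -0.00152, MIF 0.12, LOC789205 0.022, ENG 0.75, PSMB8 0.11, SCNN1A 0.075, ACACA 1.09, SREBF1 0.19, DGAT1 0.14, ACAT2 -0.32, CPT2 -0.089, ACAA1 0.013, UQCRC1 0.080, DBI -0.014, AGPAT1 0.19, PNPLA2 0.37, LTF 0.34, PGM1 0.075, CTSB 0.0079, TAPBP 0.0048, KRT7 0.085, CLDN3 0.27, CDH5 0.27, COL1A1 0.21, SPARC 0.12, JUND 0.37, AKT1 0.46, IGF2 0.20, GPX3 0.17, RBP4 0.18, PLIN1 -0.080 and RELA 0.034.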

Other observations

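Several further lists fixed in advance were not called by camera between the oil and control periods. Of 16 immediate early genes 2 rose and 5 fell, also when adjusted over the list alone (median -0.15, camera adjusted p = 0.181). ZFP36, an mRNA decay factor that limits cytokine expression, fell by 1.05 in 25 of 27 cows, JUNB by 0.59, JUND by 0.36 and FOSB by 0.21, though FOSB was 0.25 within batch 1, whose period II side was 2 arrays apart, and JUND 0.24 with array number as a covariate. Of 15 genes of insulin, growth hormone and prolactin signalling 2 rose and 4 fell, also adjusted over the list alone (p = 0.754). The growth hormone receptor GHR rose by 0.70, while the kinase AKT1 fell by 1.08, IGF2 by 0.62 and IGFBP3 by 0.64, with AKT1 at 0.69 and IGF2 at 0.20 with array number. Of 18 genes of oxidative stress defence 2 rose and 4 fell, as over the list alone (adjusted over the list alone, p = 0.334), including PRDX1 (0.25), TXNRD1 (-0.45), HMOX1 (-0.59) and GPX3 (-0.74). TXNRD1 was 0.35 and PRDX1 -0.13 within batch 1, again against those 2 arrays.

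Of 27 genes of innate inflammation 0 rose and 4 fell, or 3 adjusted over the list alone (median -0.05, p = 0.334). The falls were SAA3, TLR4 (-0.31) and the NF-kappa-B subunits NFKB1 (-0.40) and RELA (-0.30), with RELA at 0.10 with array number as a covariate. Of 14 interferon response genes 1 rose (EIF2AK2, 0.50) and 1 fell (IRF7, -0.27), also adjusted over the list alone (p = 0.427), and with array number camera called the list lower (-0.85, adjusted p = 0.0146). Of 15 genes of the unfolded protein response 1 rose (TRIB3, 0.53) and 3 fell, also adjusted over the list alone (p = 0.604), with HERPUD1 at -0.27, but 0.15 within batch 1, against 2 arrays apart, and with array number the list was called higher (0.42, adjusted p = 0.0264). Of 20 cell cycle genes 4 rose and 4 fell, also adjusted over the list alone (p = 0.838), with TYMS (-0.38) and CCND1 (-0.33) lower, and with array number the list was called lower (-0.22, adjusted p = 0.00587).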
